A study of Arabidopsis thaliana with 7 samples.

How the data were processed

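RNA from mature leaves of Arabidopsis thaliana Col-0 plants aged 3.5 weeks was measured on 7 Affymetrix ATH1 arrays, a short-oligonucleotide array on which each transcript is read by a group of probes called a probe set. The plants were grown in a 12 h photoperiod, per the labels' protocols. There was 1 array for each of untreated plants (time 0), plants sprayed with the wetting agent Silwet at 0.02% and taken after 6 h or 12 h, and plants sprayed with 0.5 mM salicylic acid (SA) in 0.02% Silwet and taken after 3, 6, 12 or 24 h. Each sample pooled leaves of a few plants, per the labels. Further biological replicates were collected but not hybridised, per the series text, which presents the experiment as an exploratory search for candidate genes. No condition and time therefore had a second array.

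The authors deposited log2 expression values, made with RMA in the affy package, per the submitters' processing notes, which give no version. RMA corrects background, quantile-normalises the arrays together and summarises the probes of a probe set, so it forces the distribution of values of all arrays to be nearly equal. The array medians lay within 0.0686 log2 units of one another. A change that moved most transcripts in 1 direction would be hidden by this step, and differences of dim probe sets are compressed. Arrays have no read depth; their number, 7, limits the precision.

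The table held 22810 probe sets, of which 64 were controls of the array maker. Genes were named only from the platform annotation table given for these arrays. In it 13513 probe sets named 1 gene, 503 named several and 8794 had none, controls included. Symbols were updated through the gene number to RefSeq's assembly GCF_000001735.4 TAIR10.1 for 13436 of the 13513, 48 carried a locus as their name, and 29 kept the name of the annotation table. Together they named 13333 loci. No coordinate was used. Many familiar genes had no named probe set. PR1, PR2, PR5, NIMIN1, WRKY70 and ICS1, which had been chosen to be reported in any case, are not analysed here for that reason.

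The main test set the 4 SA arrays against the 3 control arrays (untreated and both Silwet arrays) with limma 3.58.1 in R 4.3.3. It used lmFit and eBayes with a trended variance prior on the log2 values of the 13513 probe sets, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The error in this test is the spread between times within each arm, and in the control arm also between sprayed and unsprayed leaves. It is not the spread between biological replicates. An adjusted p below therefore says that the arms differed by more than the arrays varied within each, and nothing about variation between plants. All SA arrays were sprayed and the untreated control array was not, so the difference between the arms also holds part of the effect of the spray. The fit was tested on simulated data for this comparison, with 200 of 13513 probe sets changed and no time course within an arm. It called 46% of 50 probe sets changed by 1 log2 unit, 96% of 50 changed by 2, 96% of 50 changed by 4 and 100% of 50 changed by 6, along with 6 unchanged ones. These shares hold only for constant changes with independent noise. Genes that vary within an arm can be missed at such sizes, as AT3G01830 was at 4.56 (limma adjusted p = 0.0847).

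Differences between single arrays have no replicate, so they carry no p-value. They were described by the number of probe sets past a 2-fold difference (1 log2 unit), beside the same number for control arrays set against one another. SA at 6 h and 12 h was compared with Silwet at the same time. SA at 3 h and 24 h, which had no Silwet array, was compared with the untreated array, so those differences also hold the spray and, at 3 h, the time of day. Overlaps in the same direction between comparisons were counted only where they shared no array, beside the number that independent lists would share, n1 × n2 / N.

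The 20 gene lists and the rule for named genes were fixed before the data were examined. The lists were SA marker genes, SA synthesis and signalling, SA conjugation and turnover, detoxification, jasmonate and ethylene defence, ER protein folding, photosynthesis, circadian clock, auxin response, rapid stress (touch and wounding), heat shock, receptor-like kinases, cell cycle, senescence, camalexin and indole glucosinolates, phenylpropanoid and flavonoid, abscisic acid and cold, guard cell and epidermis markers, phloem markers, and reference genes. Of their 403 entries only 52 had a named probe set. There were 10 lists with at least 3 measured members, 7 with fewer and 3 with none. The 10 were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with 1 probe set per gene (the brightest) and Benjamini-Hochberg adjustment over the lists. For single comparisons the median of a list was placed among 10000 random lists of equal size matched on mean expression. A further 18 gene families, defined by symbol, were fixed later, after gene names, array summaries, correlations between arrays, control probe sets and the values of the first 3 probe sets had been seen, but before differences were computed. Among those first probe sets was a mitochondrion-encoded gene, which was higher on average in the SA arrays.

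Each gene that the rule picked by the size of its change lay above the median of all probe sets, 7.04, in its higher arm or array. Members of the fixed lists were given without that limit. The rule took the 12 largest rises and 12 largest falls of the main test among probe sets with an adjusted p under 0.05. It took the 10 up and 10 down with the largest value of the smaller of the 6 h and 12 h differences, whether or not they passed that test. It also took 5 up and 5 down at each of 3 h and 24 h, and members of the fixed lists as examples. Genes named outside it, including members of the families and neighbouring genes, are said to be.

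The alternatives planned for the main test were each array left out in turn, clock time as a block (in which SA 3 h, alone at its clock time, adds nothing to the difference), the 6 h and 12 h arrays alone with time as a block, no variance trend, the lowest 30% of probe sets left out, array weights, and centring on the median. The lists were also run with clock time as a block, with the mean of all probe sets of a gene and with each array left out. The single comparisons were also run with a 3-fold threshold, other control arrays and without dim probe sets. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.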

Results

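The response of Arabidopsis leaves to sprayed SA, the phenolic hormone of defence against biotrophic pathogens, was followed on 7 arrays. The 4 SA arrays were taken at 3, 6, 12 and 24 h, and the 3 control arrays were untreated leaves and leaves sprayed with the surfactant Silwet alone, taken at 6 h and 12 h. All values are log2 RMA expression values with 1 array per condition and time. An SD given for an arm is its spread over arrays (n = 4 for SA, n = 3 for control), which differ in time and, in the control arm, also in spray. Correlations between arrays over all probe sets ran from 0.898 (untreated and SA 6 h) to 0.974 (SA 3 h and SA 6 h). The control probe sets for the 2 ends of the GAPDH transcript, a measure of RNA integrity, differed between arrays. The 3′ value exceeded the 5′ value by 0.85 in the untreated array, 1.78 and 1.41 in Silwet at 6 h and 12 h, and 0.57, 0.62, 1.49 and 1.19 in SA at 3, 6, 12 and 24 h. For actin the 3′ excess was 2.40 in Silwet and 2.48 in SA at 6 h, and 1.84 in Silwet and 2.44 in SA at 12 h, so the pair that differed more was the 6 h pair by GAPDH and the 12 h pair by actin. The control probe set for 25S ribosomal RNA read 13.43 in Silwet and 12.44 in SA at 12 h, and between 8.21 and 10.30 in the remaining arrays.

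Which genes separated SA from control leaves at whatever time they were sampled was asked first. Among genes that passed the adjusted threshold, the largest rise belonged to UGT76B1 (AT3G11340), a glucosyltransferase that conjugates SA and isoleucic acid. It stood at 5.22 ± 0.44 in the control arrays and 12.58 ± 0.90 in the SA arrays, a difference of 7.36 (SE 0.50, 165-fold, limma adjusted p = 0.0021). AT3G28510, which encodes an AAA-type ATPase, rose from 4.05 ± 0.13 to 10.96 ± 0.56, by 6.92 (SE 0.31, adjusted p = 0.000666). The control levels of both genes lay below the median of all probe sets, 7.04, a range in which differences are compressed. So did those of AT1G51890, GH3.3, AT3G13950, AT1G10585, AT1G08050, GRX480 and SBT3.3, named next. The size and order of all these rises are therefore uncertain. AT1G51890, a leucine-rich repeat receptor kinase gene, rose by 4.52 (SE 0.31, adjusted p = 0.0021). The other rises among the 12 largest that passed were those of GH3.3 (4.93), an acyl amido synthetase that conjugates auxin, AT3G13950 (4.75), the bHLH gene AT1G10585 (4.45), AT4G01870 (4.43), AT1G08050 (4.42), the glutaredoxin GRX480 (4.35), which binds TGA transcription factors, the subtilase SBT3.3 (4.06), the TIR-domain gene AT1G57630 (4.02) and the chitinase gene CHI (AT2G43570, 4.01). Their adjusted p-values in limma ran from 0.0109 (AT1G08050) to 0.0458 (GH3.3). Rises as large that did not pass, such as that of AT3G01830 (4.56, limma adjusted p = 0.0847), were not ranked.

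Falls were smaller. AT5G13140 went from 9.87 ± 0.70 in the control arrays to 6.70 ± 0.81 in the SA arrays and so fell by 3.17 (SE 0.50, limma adjusted p = 0.0379). The pectate lyase gene AT3G07010 fell by 2.47 (SE 0.40), AT2G29310 by 2.37 (SE 0.31) and the beta-tubulin gene TUB5 by 2.29 (SE 0.36). The rest of the 12 largest falls that passed the adjusted threshold were in AT3G60290 (-2.10), AT2G34510 (-2.03), AT5G48460 (-1.97), AT5G45310 (-1.88), AT5G19090 (-1.76), the expansin-like gene EXLA1 (-1.71), AT5G52970 (-1.51) and AT3G57320 (-1.44). Adjusted p-values of these falls in limma ran from 0.0215 (AT2G29310 and AT3G60290) to 0.0484 (AT3G57320). Falls as large that did not pass, such as that of STOMAGEN (-3.35, limma adjusted p = 0.072), were not ranked.

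In all, 180 of 13513 probe sets passed the adjusted threshold, 139 higher and 41 lower with SA, and 2724 had an unadjusted p under 0.05. For each of the 139 all 4 SA arrays lay above all 3 control arrays, and for each of the 41 they lay below. Over all probe sets 8.67% had every SA array above and 9.41% every SA array below, where 2.86% each way is the mean over all splits of the arrays. The probe sets share these arrays, so a single split can lie far from that mean. The share in other splits was not computed. The count rested on single arrays. It was 92 without the untreated array, 27 without Silwet 6 h, 17 without Silwet 12 h, 58 without SA 3 h, 31 without SA 6 h, 44 without SA 12 h and 681 without SA 24 h. Of the 12 largest rises that passed, UGT76B1, AT3G28510 and AT1G51890 stayed under the threshold whichever array was left out, and of the 12 largest falls that passed 0 did. With clock time as a block, 164 probe sets passed, 85 of them among the 180. SA 3 h has no other array at its clock time, so that fit also leaves it out of the difference. The count without SA 3 h and with no block was 58. In the blocked fit SA 24 h is set against untreated leaves, so that part of the difference also holds the spray. Of the 24 genes named above, 10 then missed the threshold in limma: GH3.3, AT3G13950, AT1G10585, AT4G01870, GRX480, AT1G57630, AT5G13140, AT2G29310, AT3G60290 and AT5G45310, with adjusted p from 0.0540 (AT2G29310) to 0.0805 (AT4G01870). In that fit, which has 2 residual degrees of freedom in place of 5, GH3.3 differed by 4.33 (SE 0.70), GRX480 by 3.91 (SE 0.65) and AT5G13140 by -3.18 (SE 0.48).

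Of the lists fixed beforehand, 4 of the 10 tested passed in camera between SA and control arrays. Few of their planned members were measured: 7 of 34 for detoxification, 4 of 13 for SA conjugation and turnover, 3 of 21 for ER protein folding and 3 of 31 for jasmonate and ethylene defence. Detoxification genes rose (adjusted p = 0.000519, but adjusted p = 0.251 with an estimated correlation). All 7 measured members were higher on average with SA. None passed the test over all genes and 4 passed when adjusted over the list alone. The glucosyltransferase genes UGT73B5 and UGT73B4 differed most, by 3.35 (SE 0.99) and 2.98 (SE 0.88), with UGT73C1 at 1.90 (SE 0.92), each with an adjusted p above 0.1 over all genes in limma. The list of SA conjugation and turnover passed as higher (adjusted p = 0.00287, but adjusted p = 0.174 with an estimated correlation), with 4 of 4 measured members higher on average. Here 1 member passed the test over all genes, and 1 when adjusted over the list alone: UGT76B1. GH3.5 differed by 1.1 (SE 0.48), UGT74F1 by 0.33 (SE 0.12) and BSMT1, the SA methyltransferase gene, by 0.07 (SE 0.10). The mean of the 4 was 2.22 and their median 0.71, so most of the size lay in UGT76B1. Against Silwet 3 of the 4 were higher at 6 h and 3 at 12 h. Genes of protein folding in the endoplasmic reticulum rose (adjusted p = 0.00774; adjusted p = 0.251 with an estimated correlation), with 3 of 3 higher, 0 passing over all genes and 2 when adjusted over the list alone. The co-chaperone gene ERDJ3B differed by 2.3 (SE 0.49), the calreticulin gene CRT2 by 1.78 (SE 0.60) and the stress transcription factor gene BZIP60 by 1.23 (SE 0.53). The measured jasmonate and ethylene defence genes were lower with SA than in the control arrays (adjusted p = 0.0314, but adjusted p = 0.251 with an estimated correlation), with 3 of 3 lower, 0 passing over all genes and 2 when adjusted over the list alone. Silwet itself lay above untreated leaves in this list, with medians of 2.48 at 6 h and 3.15 at 12 h, so the difference includes that rise. Against untreated leaves the medians with SA were -0.36 at 3 h and -1.80 at 24 h. The defensin genes PDF1.2 and PDF1.2b differed by -2.56 (SE 1.14) and -2.77 (SE 0.95) and THI2.1 by -0.40 (SE 0.10). This last call ended without Silwet 6 h (adjusted p = 0.0694), without Silwet 12 h (adjusted p = 0.0844) or without SA 12 h (adjusted p = 0.0624), and its adjusted p with clock time as a block was 0.0298.

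The other 6 tested lists did not pass in camera. Photosynthesis genes had adjusted p = 0.317, with 7 of 7 lower, 0 of them called over all genes or adjusted over the list alone, and a median of -0.16. Abscisic acid and cold genes had adjusted p = 0.383, with 3 of 3 lower, 0 called either way and a median of -1.16. With clock time as a block both passed, at adjusted p = 0.0122 and adjusted p = 0.0216, and without such a block, with an estimated correlation, each had adjusted p = 0.756. In the auxin list (adjusted p = 0.471, test direction down) the median was -0.10 and the mean 0.72, because GH3.3 rose by 4.93 while IAA29 fell by 1.03 (SE 0.17, adjusted p = 0.0401). Phenylpropanoid and flavonoid genes (adjusted p = 0.471, 5 of 5 lower, 0 called), heat shock genes (adjusted p = 0.739, 2 of 3 higher, 0 called) and reference genes (adjusted p = 0.855, 1 of 3 higher, 0 called) did not pass either. In the heat shock list the chaperone-associated gene ROF2 stood apart, at 3.38 (SE 1.4, adjusted p = 0.232). The 7 smaller lists were not tested as groups. Among SA marker genes GRX480 rose and WRKY53 differed by 2.35 (SE 1.42, adjusted p = 0.402). SAG101, of the SA signalling list, differed by 1.4 (SE 0.26, adjusted p = 0.0565) and IGPS, an enzyme of tryptophan synthesis in the camalexin list, by 1.99 (SE 0.42, adjusted p = 0.0662). Values for the guard-cell gene FAMA (-0.72, adjusted p = 0.2), the clock gene GI (0.17, adjusted p = 0.966), the senescence gene SAG29 (-0.17, adjusted p = 0.417) and the rapid stress genes ZAT10 (1.85, adjusted p = 0.45) and ORA47 (-0.08, adjusted p = 0.955) did not pass. FAMA, SAG101 and IGPS were each the 1 measured member of a list, so adjusting over the list alone changes nothing. Each had an unadjusted p under 0.05 in limma, as did 2724 of all 13513 probe sets. The receptor-like kinase, cell cycle and phloem lists had no member with a named probe set and are not analysed here.

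**Figure D1:**
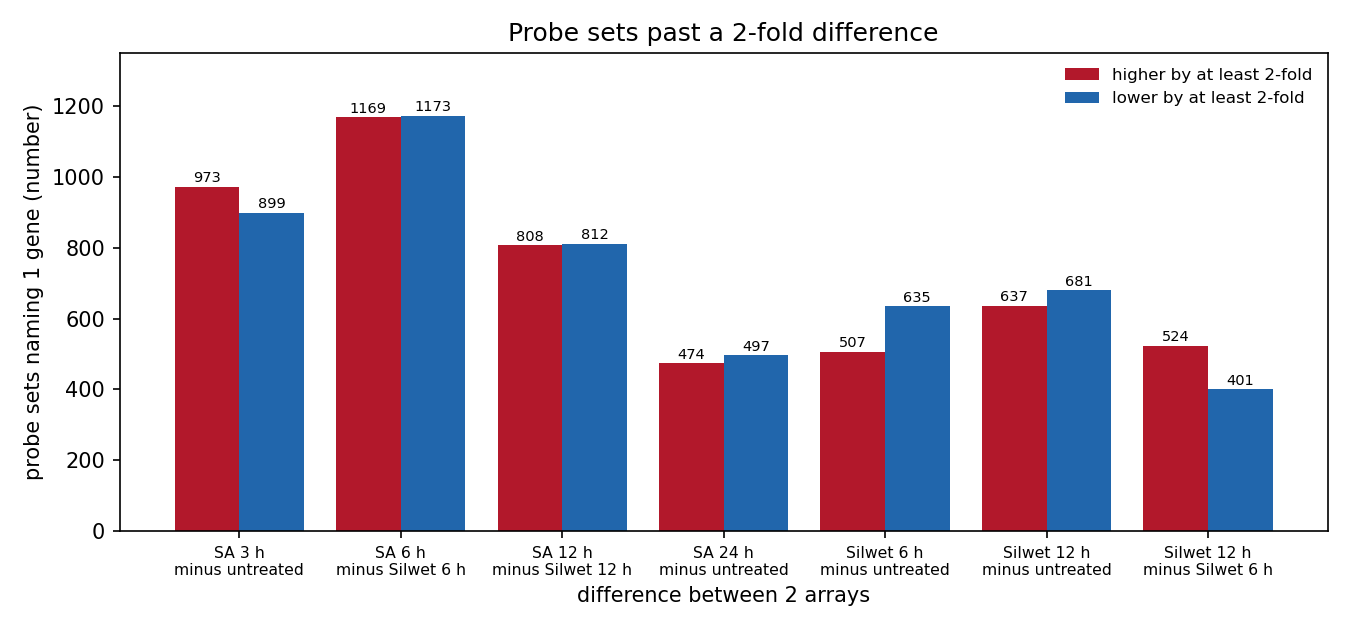
Number of probe sets naming 1 gene (vertical axis, starting at 0) at least 2-fold higher (red) or lower (blue) in each difference between 2 single arrays (horizontal axis). SA minus Silwet gave 1169 and 1173 at 6 h and 808 and 812 at 12 h, against 524 and 401 between the Silwet arrays.

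The effect of SA at a matched time was read from SA and Silwet arrays from the same time, at 6 h and at 12 h. UGT76B1 was higher with SA by 8.55 at 6 h and 7.39 at 12 h, and AT3G28510 by 7.40 and 7.30. The smaller of both differences was next largest for AT3G13610 (5.25 and 5.10), whose product hydroxylates feruloyl-CoA in coumarin synthesis, AT1G10585 (6.10 and 4.92), the calmodulin-like gene AT3G01830 (6.38 and 4.65), CHI (4.86 and 4.58), AT5G38900 (4.51 and 5.12), the calmodulin-like gene CML37 (4.79 and 4.51), AT1G57630 (5.01 and 4.38) and AT1G51890 (4.80 and 4.37). For AT3G01830 and CML37 the Silwet arrays lay below the untreated array. Silwet minus untreated was -3.95 at 6 h and -3.14 at 12 h for AT3G01830, and -2.23 and -2.44 for CML37.

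The 10 genes lower at both times included STOMAGEN (-4.35 at 6 h and -4.00 at 12 h), which encodes a peptide that promotes stomatal development, and the GDSL lipase genes AT1G29660 (-3.82 and -3.92) and AT3G16370 (-3.08 and -4.70). AT2G10940 (-4.54 and -4.30), AT5G13140 (-3.60 and -4.11) and AT5G44020 (-3.43 and -3.28) were among them too. For AT2G43550, AT3G28220, AT1G12845 and AT1G78450 the Silwet arrays were higher than the untreated array. AT2G43550 was 4.92 and 4.05 higher in Silwet at 6 h and 12 h than in untreated leaves, and lower with SA than with Silwet by -4.44 and -4.31. AT3G28220 showed 2.28 and 0.83 against -3.70 and -4.18, AT1G12845 showed 3.08 and 1.43 against -4.41 and -3.28, and AT1G78450 showed 1.08 and 2.40 against -3.22 and -3.64.

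At 6 h 1169 probe sets were at least 2-fold higher and 1173 at least 2-fold lower with SA than with Silwet, and at 12 h 808 and 812. The Silwet arrays differed from each other in 524 higher and 401 lower at 12 h than at 6 h. Past 2-fold at both times were 610 higher and 551 lower, against 69.9 and 70.5 for independent lists; the pairs share no array. Of the 1169, 1098 had the same sign at 12 h and 5 were at least 2-fold lower, namely UGT73B1, Hop3, Fes1A, AT1G64380 and AT2G20670, named after their values were seen. The differences at both times correlated over probe sets with Pearson's r of 0.785 and Spearman's rho of 0.673, with genes not independent replicates. With no replicate, these counts describe these arrays and carry no p-value. The 3′ excess of GAPDH was 1.78 in Silwet against 0.62 in SA at 6 h, and 1.41 against 1.49 at 12 h, and that of actin was 2.40 against 2.48 at 6 h and 1.84 against 2.44 at 12 h.

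**Figure D2:**
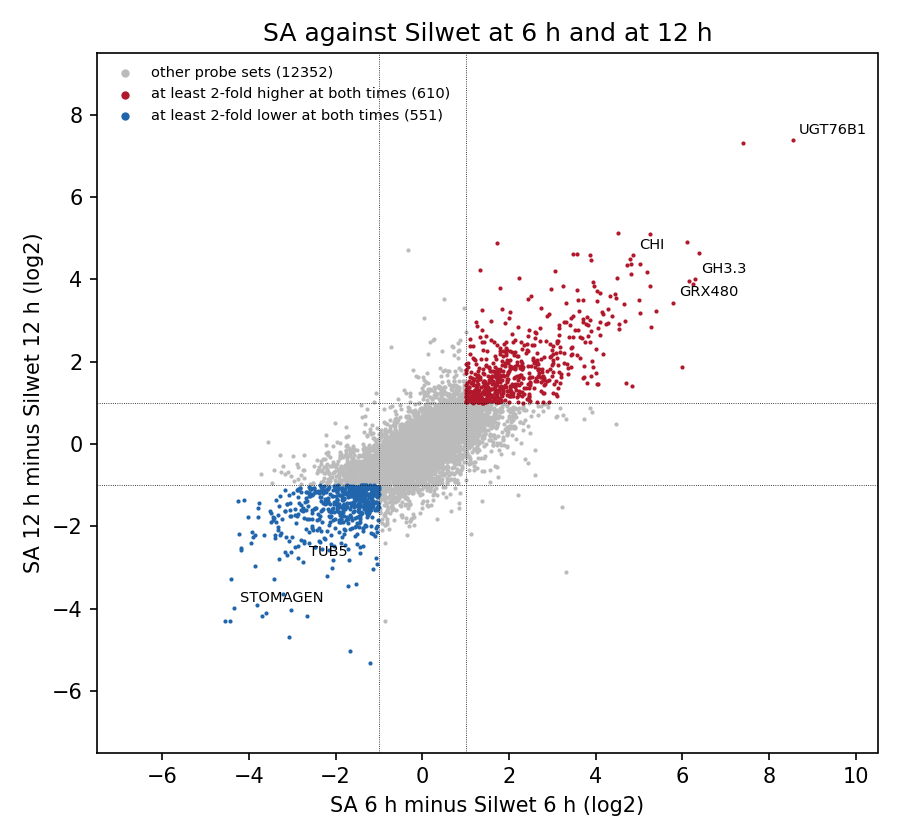
Log2 difference between SA and Silwet at 6 h (horizontal axis) and at 12 h (vertical axis), 1 point per probe set naming 1 gene. The 610 probe sets at least 2-fold higher at both times are red, the 551 lower at both are blue, and dotted lines mark 2-fold.

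By list, the 7 detoxification genes had a median of 1.28 at 6 h, above 99.99% of random lists, and 0.87 at 12 h, above 99.94%. Genes of ER protein folding had medians of 2.1 (99.31%) and 1.84 (99.69%). In this list Silwet against untreated leaves gave medians of 0.94 at 6 h and -0.93 at 12 h, with 1 of 3 members higher at 12 h. The 12 h difference thus includes in part a low level in Silwet. SA against untreated leaves gave 1.78 at 3 h and 1.41 at 24 h, with 3 and 2 of 3 members higher. For jasmonate and ethylene defence the median was -1.21 at 6 h, above 1.36% of random lists, and -5.03 at 12 h, above 0%. PDF1.2 was -1.21 at 6 h and -5.32 at 12 h, and PDF1.2b -1.68 and -5.03. In that list Silwet itself lay above untreated leaves, with medians of 2.48 at 6 h and 3.15 at 12 h. The abscisic acid and cold list had medians of -0.86 at 6 h and -1.04 at 12 h, above 10.4% and 2.08% of random lists. COR15A stood 2.2 higher in Silwet 6 h than in untreated leaves and -0.85 with SA against Silwet at that time.

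Early and late times were read against the untreated array. At 3 h the largest differences were again those of UGT76B1 (7.41), AT3G28510 (6.57) and GH3.3 (6.27), followed by AT4G39670 (5.81), of a glycolipid transfer protein family, and AT1G26380 (5.72), of a FAD-linked oxidase. At 24 h AT3G28510 stood 6.48 and UGT76B1 5.64 above untreated leaves, followed by AT5G39520 (5.02), the osmotin gene OSM34 (4.49) and AT1G76960 (3.94). OSM34 lay between 4.96 and 5.24 in the 6 other arrays and at 9.45 at 24 h. AT5G39520 was at 5.71 untreated and 5.61, 7.04, 10.32 and 10.73 with SA at 3, 6, 12 and 24 h, while the Silwet arrays read 5.71 and 6.10.

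The genes lowest against untreated leaves at these times were also lower than untreated with Silwet, to differing degrees. At 3 h they were AT2G27420 (-5.79), AT1G60590 (-5.30), both probe sets of AT5G54130 (-4.72 and -4.68) and the xyloglucan endotransglucosylase gene XTH19 (-4.39). In Silwet the same 5 probe sets read -5.45, -3.42, -5.35, -5.85 and -4.51 against untreated at 6 h, and -6.10, -2.29, -5.31, -5.43 and -4.46 at 12 h, so AT1G60590 was not as low with Silwet as with SA. At 24 h they were XTH19 (-4.21), AT1G64380 (-4.15), AT1G05575 (-3.72), AT4G37290 (-3.60) and AT4G15680 (-3.42), with -4.51, -3.54, -4.18, -3.14 and -2.88 in Silwet at 6 h and -4.46, -1.61, -3.81, -3.30 and -1.80 at 12 h. Against the mean of both Silwet arrays, a control chosen after seeing the data, XTH19 was 0.10 higher at 3 h and 0.27 higher at 24 h.

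Past 2-fold of the untreated array were 973 higher and 899 lower probe sets at 3 h and 474 and 497 at 24 h. Silwet alone gave 507 higher and 635 lower at 6 h and 637 and 681 at 12 h, more than SA at 24 h. The 3 h and 24 h comparisons share the untreated array and have no replicate, so overlap in the same direction between them was not counted. Compared with the 6 h pair, which shares no array with them, 697 of the 1169 probe sets higher at 6 h were also at least 2-fold higher at 3 h (84.2 for independent lists), and 305 at 24 h (41.0). In the opposite direction, 28 of the 1169 were at least 2-fold lower at 3 h and 90 at 24 h. Of the 1173 lower at 6 h, 485 were lower at 3 h (78.0) and 162 at 24 h (43.1), while 12 and 16 were at least 2-fold higher.

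**Figure D3:**
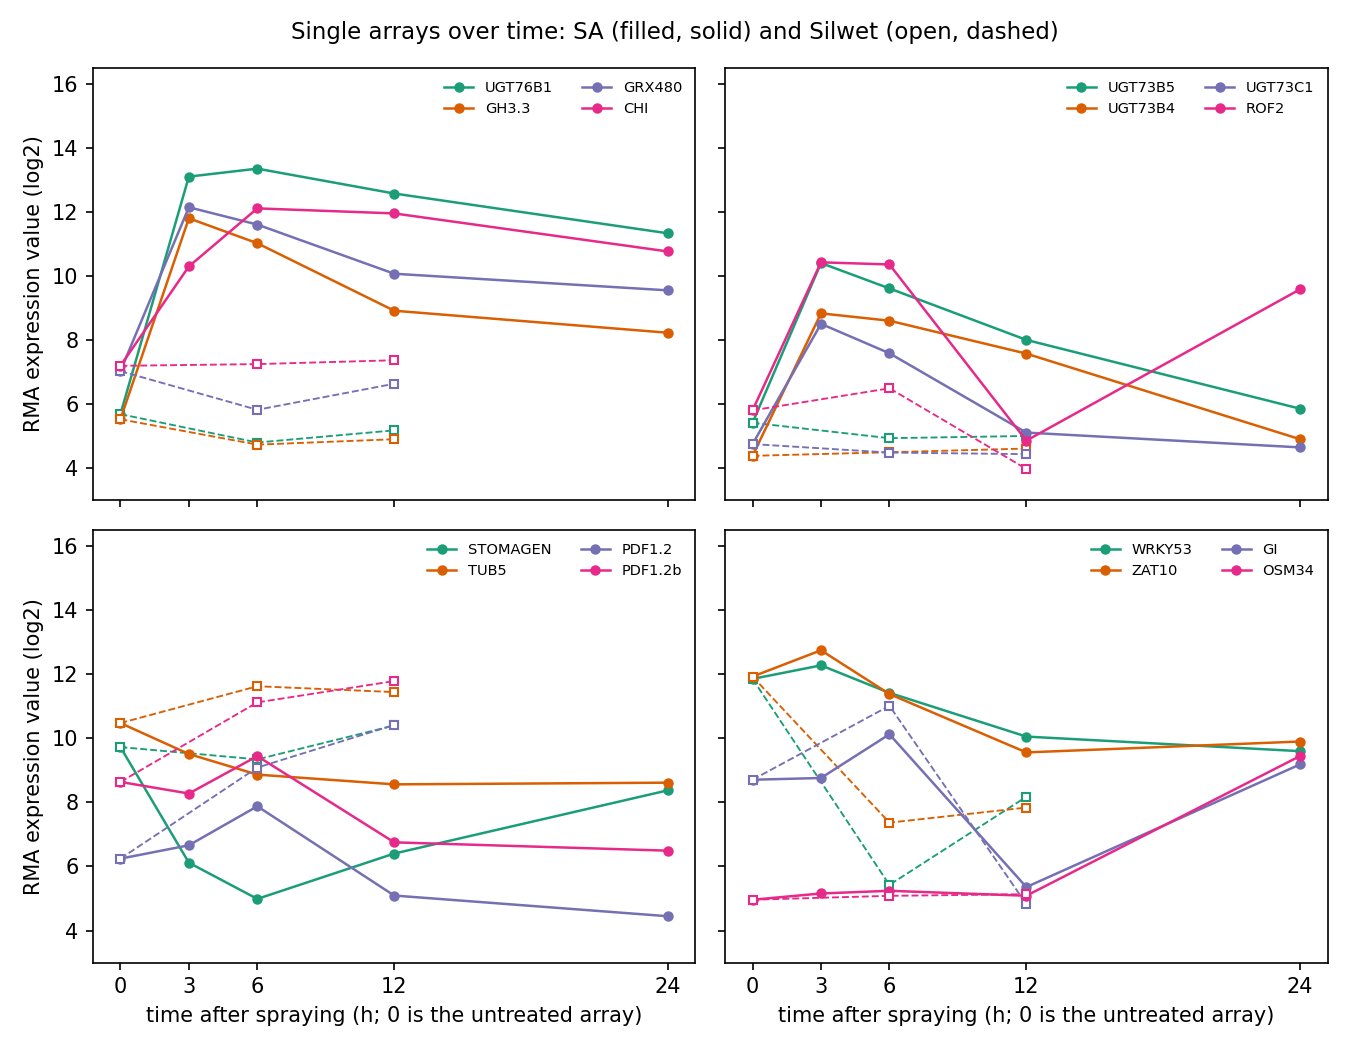
RMA expression values (vertical axis, log2) of 16 genes over time after spraying (horizontal axis, h) on single arrays, SA filled with solid lines and Silwet open with dashed lines, both starting from the untreated array at 0. UGT76B1 stayed high at 24 h (11.33), UGT73B5 went from 10.40 at 3 h to 5.85 at 24 h, and OSM34 was high at 24 h alone (9.45).

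Courses over time differed among the genes raised with SA. The 610 probe sets higher at both matched times had a median of 1.67 above untreated at SA 3 h, 1.81 at 6 h, 1.55 at 12 h and 0.88 at 24 h, and of -0.12 and -0.11 in Silwet at 6 h and 12 h. The 551 lower ones had medians of -1.02, -1.57, -1.29 and -0.61 with SA and 0.17 and 0.22 with Silwet. Both groups were picked by SA minus Silwet at 6 h and 12 h, which pushes the medians of those 4 arrays apart. The 3 h and 24 h arrays played no part in the choice. Medians at 6 h and 12 h therefore cannot be set against those at 3 h and 24 h. UGT76B1 read 13.10, 13.34, 12.57 and 11.33 over the 4 SA times, and GH3.3 11.80, 11.02, 8.91 and 8.22. CHI (10.29, 12.10, 11.95 and 10.76) and AT3G13610 (9.05, 11.01, 10.86 and 8.59) were highest at 6 h. UGT73B5 (10.40, 9.61, 8.0 and 5.85) and UGT73C1 (8.50, 7.58, 5.11 and 4.65) were close to their untreated values of 5.41 and 4.75 by 24 h. STOMAGEN read 9.72 untreated and 6.12, 4.99, 6.40 and 8.38 with SA. None of these differences between times was tested.

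What spraying and clock time did without SA was read from both Silwet arrays against the untreated array. At 6 h 507 probe sets were at least 2-fold higher and 635 lower, and at 12 h 637 and 681, with no replicate. WRKY53 was at 11.85 in untreated leaves and 5.42 and 8.17 in Silwet at 6 h and 12 h, and ZAT10 at 11.92, 7.37 and 7.84. With SA at 3, 6, 12 and 24 h WRKY53 read 12.27, 11.42, 10.05 and 9.60 and ZAT10 12.74, 11.38, 9.56 and 9.90. The clock gene GI read 8.70 untreated, 11.01 and 4.83 in Silwet at 6 h and 12 h, and 8.76, 10.12, 5.36 and 9.19 with SA, so that both arms were high at 6 h and low at 12 h. UGT78D2 of the flavonoid list was 11.28 untreated, 8.21 and 7.81 with Silwet, and 10.85 with SA at 24 h.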

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

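The tests of time of day, of a low level in the Silwet arrays and of neighbours among the genes raised at both matched times were chosen only after the result was seen.

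AT1G64380 was higher with SA than with Silwet by 1.37 at 6 h and lower at 12 h (-1.39). AT1G05575 stood 1.80 above untreated leaves at SA 3 h and below them at SA 24 h (-3.72). Both drew attention because 2 times moved in opposite directions; the difference was not tested, and each value compares single arrays. In all, 7 probe sets went past 2-fold in opposite directions at 6 h and 12 h, comparisons that share no array. At 3 h and 24 h, comparisons that share the untreated array, 36 did so, 31 of them higher at 3 h and lower at 24 h, as AT1G05575 was. That gene read 9.57 untreated, 5.39 and 5.76 in Silwet at 6 h and 12 h, and 5.85 at SA 24 h. Its fall against untreated leaves was thus also present with Silwet alone. AT3G16530, named after its values were seen, read 11.20 untreated, 11.77 and 11.24 in Silwet, and 9.22 at SA 24 h. A fall at 24 h against untreated leaves is therefore not by itself a reversal with SA. Besides AT1G64380, those higher at 6 h and lower at 12 h were UGT73B1 (1.13 and -2.19), Hop3 (3.32 and -3.11), Fes1A (3.23 and -1.54) and AT2G20670 (2.22 and -1.24), and those with the opposite order were AT5G50915 (-1.07 and 1.25) and AT3G26490 (-1.11 and 1.03), all named after their values were seen. Hop3, a co-chaperone gene, read 4.78 and 7.91 in Silwet at 6 h and 12 h and 8.10 and 4.81 with SA.

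Probe sets outside the analysis, those that the annotation used here left unnamed or gave several genes, also differed with SA. Of these 9233, 683 were at least 2-fold higher than Silwet at both 6 h and 12 h, against 113.1 for independent lists, and 476 were lower, against 78.2. The higher ones made up 7.4%, compared with 4.51% of the probe sets naming 1 gene. Between the Silwet arrays, 428 of the 9233 were at least 2-fold higher and 413 lower at 12 h.

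For the count of 180 probe sets in the all-arrays test, 1 of the 35 splits of the 7 arrays into 4 and 3, the real one, gave as many calls. The arrays are ordered times, some of which share a clock time, so they are not exchangeable. This rank therefore cannot exclude a random division of the arrays. The highest of the other splits gave 160, and it set the SA arrays of 3, 6 and 12 h against the other 4, with SA 24 h among the controls. By the number at an unadjusted p under 0.05, that split gave 2973 and the real one 2724, so 2 of the 35 reached the real value and chance is not excluded by that count either. SA 24 h and the untreated array correlated at 0.964 over probe sets, so that split follows a structure of the samples.

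The first pattern weighed was a group of genes far higher in untreated leaves than in both Silwet arrays, by at least 2 log2 units in 145 probe sets. Time of day could produce it, since SA 24 h was taken at the same clock time as the untreated array. Of the 58 among them that moved by under 1 log2 unit with SA at 6 h and 12 h, 31% lay within 1 log2 unit of untreated at SA 24 h, and their median there was -1.61, against -2.87 in Silwet at 6 h, so that time of day and the spray cannot be told apart for these 58 without a Silwet array at 24 h. SA 24 h was also below untreated leaves for the stress genes WRKY53 (-2.25), ZAT10 (-2.03) and AT3G10930 (-2.47), but these 3 were picked after their values were seen and themselves differed with SA at 6 h and 12 h, so they decide nothing about clock time. Handling of the untreated plants at harvest may have raised such genes, a hypothesis for which no test was run.

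The second pattern was the rise of 610 probe sets over Silwet at both 6 h and 12 h, which could come from a low level in the Silwet arrays alone. Of the 610, 434 (71.1%) also lay 2-fold above untreated leaves at both times, so that for these SA was above both kinds of control. The same SA arrays had served to pick the 610, which raises this share. For the rest of the 610, SA and a low Silwet level cannot be told apart, since the untreated array differs in time and spray. AT3G01830 and CML37 show both, with SA above untreated and Silwet below it.

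The third pattern was neighbouring genes: among the genes higher in the all-arrays test there was 1 adjacent pair, AT5G45500 and AT5G45510 (named after their values were seen), within what chance placement gives (mean 0.71 of 10000 draws); with plain probe sets alone there was again 1, and with no excess the marked probe sets had nothing to account for. Among the 602 genes higher at both matched times there were 26 adjacent pairs, against a mean of 14.1 and a highest of 28 in 10000 random draws, 19 of which gave as many. That is more than nearly all draws gave, but the limit applied here was chosen after the result was seen. The stricter limit fixed beforehand for the called genes, more pairs than in every draw, was not met, so chance placement is not excluded. Without probe sets marked as matching several genes the number was 26 as well, reached by 22 draws. The 547 genes lower at both times showed no such excess, with 17 pairs against a mean of 11.5, a number that 777 draws reached. Tandem copies under shared control, such as UGT73B5 and UGT73B4 or SBT3.5, AT1G32950 and SBT3.3 (pairs named after their values were seen), may account for the excess, but cross-hybridisation between similar copies on unmarked probe sets stays open.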

How the results depend on the processing

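The alternatives that used all probe sets but controls, the mean of both Silwet arrays as control for 3 h and 24 h, and the added requirement of 2-fold over untreated were chosen only after seeing the data. The count of 180 became 305 of 9459 without dim probe sets, 440 with array weights and 395 of 22746 over all probe sets but controls, and ranged from 17 to 681 when single arrays were left out (92 without untreated, 27 without Silwet 6 h, 17 without Silwet 12 h, 58 without SA 3 h, 31 without SA 6 h, 44 without SA 12 h, 681 without SA 24 h). Each such fit has fewer arrays, and why SA 24 h acts in the opposite direction was not tested. With clock time as a block, which also drops SA 3 h from the difference (164), the 6 h and 12 h arrays alone (238), no variance trend (140) and median centring (191) it stayed within 1.5 times, although only 85, 73, 117 and 179 of those were among the 180. The 24 named genes kept their direction in all of these fits. Of the 24, 14 stayed under the threshold with clock time as a block, 13 with the 6 h and 12 h arrays alone and 15 without the trend, and 24 in the other fits with all arrays.

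A 3-fold threshold left 1105 probe sets at 6 h, 617 at 12 h and 433 at both, fewer by construction. Those past 2-fold at both times numbered 2320 over all probe sets and 749 when 2-fold over or under untreated was also required; other control arrays or leaving out dim probe sets changed no single-array count by 1.5 times. Against the mean of both Silwet arrays the sign turned for AT5G54130 at 3 h (0.62 and 0.95 for its 2 probe sets), XTH19 at 3 h (0.10) and 24 h (0.27) and AT1G05575 at 24 h (0.27), since Silwet was as low as SA there.

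Of the gene lists, 4 passed in camera at the preset correlation, 0 with an estimated correlation (where SA conjugation had the lowest unadjusted p, 0.0174), 4 with the mean of all probe sets of a gene, 6 with clock time as a block, and 3 to 4 when single arrays were left out. The cause of these changes was not tested. With 1 array per condition no alternative tests variation between plants, and differences between dim probe sets are the least certain, being close to background.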

Other observations

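The 18 gene families below were chosen by symbol before differences were computed, but after the first 3 probe sets had been seen; no test in this part was chosen after its result was seen, but the family members given as examples fall outside the rule for named genes and were picked after their values were seen, except where they are named in the report.

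UDP-glycosyltransferases attach sugars to hormones and small molecules. As a family they passed as higher in the all-arrays test (camera adjusted p = 0.0121, but adjusted p = 0.568 with an estimated correlation). Of 47 members 27 were higher and 20 lower, with a median of 0.15 and a mean of 0.52. Against untreated leaves the median was 0.41 at 3 h and 0.20 at 24 h, with 29 and 27 members higher, above 100% and 99.98% of random lists. Against Silwet it was 0.18 at 6 h, with 27 members higher, and -0.01 at 12 h, with 21 higher, above 99.95% and 74.2%. In limma 3 members passed over all genes: UGT76B1, UGT73D1 (3.47, SE 0.50, adjusted p = 0.0271) and UGT87A2 (2.32, SE 0.23, adjusted p = 0.008). UGT76B1 also belongs to the SA conjugation list, so the call of this family is not independent of that list. Genes of vesicle traffic named SEC or VPS (12 of 18 higher), of ubiquitin conjugation (23 of 33 higher) and of the mitochondrial genome (12 of 15 higher) rose at adjusted p = 0.0294 each, with 0 members passing over all genes. With an estimated correlation these had adjusted p = 0.568, adjusted p = 0.568 and adjusted p = 0.576. In the same order, their medians against untreated leaves were 0.35, -0.004 and 0.287 at SA 3 h and 0.008, 0.057 and -0.015 at SA 24 h. Against Silwet they were 0.379, 0.354 and 0.277 at 6 h and 0.206, 0.379 and 0.202 at 12 h. Silwet against untreated leaves gave 0.024, -0.053 and -0.158 at 6 h and 0.0, -0.053 and -0.161 at 12 h. The vesicle traffic call ended without SA 6 h (adjusted p = 0.0716) or SA 12 h (adjusted p = 0.0825). The ubiquitin call ended without Silwet 6 h (adjusted p = 0.114), Silwet 12 h (adjusted p = 0.0684), SA 6 h (adjusted p = 0.0716), SA 12 h (adjusted p = 0.0825) or SA 24 h (adjusted p = 0.0541). The mitochondrial call ended with clock time as a block (adjusted p = 0.0794) and without Silwet 6 h (adjusted p = 0.154), SA 3 h (adjusted p = 0.0916) or SA 12 h (adjusted p = 0.0825).

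Tubulins, xyloglucan endotransglucosylases with expansins, and chloroplast-encoded genes passed as lower in the all-arrays test. Of 7 tubulin genes 6 were lower (adjusted p = 0.0294; adjusted p = 0.568 with an estimated correlation), with TUB5 called over all genes, TUB6 at -1.22 (adjusted p = 0.114) and TUA1 going the other way at 0.51 (adjusted p = 0.455). The tubulin call ended without SA 24 h (adjusted p = 0.0916). Against Silwet at the same time the tubulin medians with SA were -1.08 at 6 h and -1.48 at 12 h, above 0.76% and 0% of random lists. Silwet against untreated leaves gave 0.105 and 0.017. Of 27 wall-loosening genes 25 were lower (adjusted p = 0.0121; adjusted p = 0.568 with an estimated correlation), EXLA1 being called and EXPA8 standing at -1.99 (adjusted p = 0.119). That call ended without the untreated array (adjusted p = 0.217), and the family was also lower in Silwet than in untreated leaves, with medians of -0.23 at 6 h and -0.25 at 12 h. Against Silwet at the same time its medians with SA were -0.23 at 6 h and -0.20 at 12 h, above 2.52% and 1.37% of random lists. Of 54 chloroplast-encoded genes 51 were lower (adjusted p = 0.0121; adjusted p = 0.638 with an estimated correlation), by a median of -0.20, with 0 called over all genes. Without the untreated array the adjusted p was 0.728 and without SA 24 h 0.0676. Their medians in Silwet against untreated leaves were -0.38 at 6 h and -0.32 at 12 h, each above 0% of random lists. With SA against Silwet at 6 h and 12 h the medians were -0.07 and -0.11, above 51.9% and 29.3%. The chloroplast call thus rested largely on the untreated array, and against Silwet at a matched time these genes showed little shift.

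The remaining 11 families did not pass in camera: Aux/IAA and auxin GH3 genes (adjusted p = 0.0563), WRKY factors (0.108), TRICHOME BIREFRINGENCE-LIKE genes (0.131), glutamate receptors (0.175), autophagy genes (0.177), serine carboxypeptidase-like genes (0.342), SWEET transporters (0.412), tau glutathione S-transferases (0.412), beta-glucosidases (0.578), AGAMOUS-like factors (0.663) and cytochromes P450 (0.885). Other settings brought 2 of these under the threshold. Aux/IAA and auxin GH3 genes, with a median of -0.14 and a mean of 0.16, passed as lower with clock time as a block (adjusted p = 0.0365) and without Silwet 6 h (adjusted p = 0.0398), Silwet 12 h (adjusted p = 0.0487) or SA 3 h (adjusted p = 0.0257), and had adjusted p = 0.57 with an estimated correlation. WRKY factors passed as higher without the untreated array (adjusted p = 0.0206), but had adjusted p = 0.403 without Silwet 6 h and, with all arrays, adjusted p = 0.568 with an estimated correlation. Their median against Silwet was 1.36 at 6 h and 0.18 at 12 h, above 99.9% and 81.4% of random lists. Against untreated leaves it was 0.18 at SA 3 h and -0.67 at SA 24 h (80.6% and 0.24%), and -2.09 and -1.17 in Silwet at 6 h and 12 h (0% and 0.02%), so the 6 h difference includes a low level in Silwet. Single members rose in some of these, namely scpl16 (2.33, adjusted p = 0.0109), BGLU45 (1.98, adjusted p = 0.0351) and CYP71B23 (2.82, adjusted p = 0.0215) in limma. ATG8B (2.05, adjusted p = 0.0897) and ATG8H (1.71, adjusted p = 0.108) stood apart among autophagy genes without passing.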
